A study of Arabidopsis thaliana with 15 samples.

How the data were processed

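RNA was measured by sequencing in 15 libraries of whole Arabidopsis thaliana seedlings, wild type of the Col ecotype, at 10 days of age. There were 3 libraries in each of 5 groups: solvent at 0 h, 2 h and 4 h, and 5 µM GR24 4DO at 2 h and 4 h. The data were 1 deposited table of RPKM (reads per kilobase of gene and per 1e6 reads assigned to genes), which the authors computed from read counts per gene. Per the submitters' processing notes, reads were mapped with STAR to the TAIR10 genome and counted with featureCounts, and DESeq was used for differential expression. Their versions, the handling of reads that map to several places and the strand of counting are not given in the sources used here. Near-identical genes, such as copies of LHCB1, LHCB2 and SAUR genes, may therefore share or lose reads.

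The table held 32678 named genes and 1 entry with no gene name, which was left out. Of these genes, 6698 were at 0 in every library, and so were all 279 organelle-encoded genes (133 chloroplast and 146 mitochondrial), so these say nothing about organelle transcripts. All 347846 values above 0, in 25980 genes, were whole numbers of reads once multiplied by a gene length and a library total, within 0.02 reads. With altered totals this held for 0 of 1000 genes tried. The recovered totals gave depths of 24.4 to 37.4 M reads (1 M is 1e6). The recovered lengths equalled the exon length of the reference at hand (TAIR10.1) for 17.3% of 25858 genes, with a median ratio of 0.91, so no coordinates are given. Gene names came from that reference, and for 16 genes from the lists described below. With 3 reads in a gene of 1 kb as a floor, values under 0.08 to 0.123 RPKM rest on too few reads. Such floors cover counting error only.

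The plan named a test for raw counts and another for RPKM. As the deposited table held RPKM, the test for RPKM was used, and reads recovered from it were used only in an added alternative, although they would have allowed a count analysis. Genes with at least 1 RPKM in 3 or more libraries were tested, 19155 in all. The limma package (3.58.1) was run in R 4.3.3 on log2(RPKM + 1), with 1 fit of all 15 libraries by group and a trend of variance with level. Benjamini-Hochberg adjusted p under 0.05 counted as called, with no minimum fold. Contrasts were GR24 4DO against solvent at 2 h and at 4 h, the difference between these responses, and solvent at 2 h and at 4 h against 0 h. The median standard error of a log2 difference was 0.093, and 0.131 for the difference of responses. Overlap of calls was tested with Fisher's exact test over genes.

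Lists of genes were fixed, together with the tests, the alternatives and the rule for naming genes, before the data were examined. There were 25: strigolactone, karrikin, flavonoid and anthocyanin, auxin, cytokinin, gibberellin, abscisic acid, jasmonate, salicylic acid, ethylene, brassinosteroid, early wound and defence, hypoxia, sugar starvation and bud dormancy, nitrate, phosphate, morning-phased clock, afternoon- and evening-phased clock, light-harvesting, light signalling, heat shock, xenobiotic detoxification, cell cycle, and root and shoot cell markers. Each was tested with camera, which compares a list with the other genes. Camera was run at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Each list was also tested with fry, which tests for a change of the list itself. P-values were adjusted over the lists within a contrast. Genes were named by rule. For GR24 4DO contrasts these were called members of the strigolactone and karrikin lists, the 8 highest and 8 lowest log2 differences among called genes with at least 1 RPKM in the higher group and no overlap between groups, and up to 4 members per list with the smallest adjusted p. For solvent contrasts these were the 5 highest and 5 lowest and up to 3 per list, and for the difference of responses the 5 smallest adjusted p in each direction.

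Whether replicate numbers pair the samples was checked from the correlation of residuals. At 2 h the correlations of GR24 4DO and solvent libraries with the same number were 0.179, 0.133 and 0.101, each above those with another number. These are low, and such an order can arise by chance with 3 libraries per group, so pairing is not established. The block by replicate is given beside results at 2 h. At 4 h the correlations were -0.183, 0.491 and 0.407, and at least 1 pair was under 0.1 in each solvent contrast too.

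Alternatives planned for RPKM were quantile normalization, limma without the trend, no filter, a filter at 5 RPKM, a pseudocount of 0.1, only the compared groups, the replicate block, a minimum change of 2-fold, and each library left out in turn. Added after the data were seen were limma-voom on the recovered reads, the same with a wider filter of 5 reads in 3 libraries, median-of-ratios scaling, near-identical pairs averaged, the block in the 6 libraries of 2 h alone, and removal of each library's trend with gene length, with and without the block. The tests were also tested on simulated data in which 50 genes were changed at each fold. At 2 h, 76, 96, 96 and 100% were found at 1.5-, 2-, 3- and 4-fold, with 13 false among 197 calls. At 4 h, 60, 90, 100 and 100% were found, with 4 false among 179. The simulated libraries were drawn independently, without near-identical pairs, trends with gene length or shared replicate effects. These shares may therefore not hold for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, tables and figures.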

Results

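Transcript levels were measured by RNA sequencing in whole wild-type seedlings of Arabidopsis thaliana (Col ecotype) at 10 days of age. After 2 h of adjustment in liquid culture medium, seedlings received 5 µM GR24 4DO, a synthetic strigolactone whose stereochemistry is that of the natural strigolactone 4-deoxyorobanchol, or solvent. There were 5 groups of 3 libraries: solvent at 0 h, 2 h and 4 h, and GR24 4DO at 2 h and 4 h. The table held RPKM values, from which the reads assigned to genes could be recovered as whole numbers. Replicates 1, 2 and 3 held 26.8, 24.4 and 33.4 M reads (1 M is 1e6) in solvent at 0 h, 24.8, 37.4 and 28.7 M in solvent at 2 h, and 26.8, 28.7 and 25.2 M in solvent at 4 h. They held 24.8, 26.1 and 25.1 M with GR24 4DO at 2 h, and 26.4, 30.5 and 36.9 M with GR24 4DO at 4 h. At these depths, 1 read in a gene of 1 kb was worth 0.0267 to 0.0409 RPKM, and between 18370 and 18891 genes per library reached 1 RPKM. RPKM values below are means ± SD of 3 libraries, and differences are on the log2 scale of RPKM + 1, which understates the change of low genes. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

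Time point separated the libraries more than treatment did. The first principal component held 46.3% of the variance, with the 0 h libraries between -39.1 and -34.3, the 6 libraries of 2 h between -10.6 and 6.12, and the 6 libraries of 4 h between 16.6 and 21.8. The second component held 20.9%. In 3 groups, a pair of replicates was closer than all other pairs. For solvent 4 h replicates 1 and 3 the chi-square of their reads was 1.13 per degree of freedom (p = 3.3e-35). For solvent 2 h replicates 2 and 3 it was 1.74, and for GR24 4DO 4 h replicates 1 and 2 it was 1.87, against 3.82 to 19.23 for the other 12 pairs. The test excludes the same reads in both columns but not 1 RNA sample behind a pair. All 15 libraries were counted as separate samples because they are labelled as replicates, and counts and list calls that changed with the pairs averaged are given beside the results.

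The comparison at 2 h asked which transcripts respond first to GR24 4DO. Several genes of strigolactone and karrikin signalling rose. DLK2, a paralogue of the receptor genes D14 and KAI2, rose from 24.8 ± 1.75 RPKM in solvent to 45.7 ± 1.98 RPKM with GR24 4DO (n = 3 and 3, log2 difference 0.86, SE 0.06, adjusted p = 9.31e-06). SMXL7 and SMXL8, which encode transcriptional repressors destroyed when D14 binds strigolactone, rose from 10.8 ± 0.274 to 19.7 ± 1.39 RPKM and from 1.25 ± 0.0962 to 3.08 ± 0.274 RPKM, with log2 differences of 0.81 and 0.86. Among karrikin pathway genes, SMXL2, which encodes a related repressor, rose from 13.4 ± 0.345 to 21.2 ± 0.581 RPKM. The F-box gene KUF1 rose from 11.1 ± 0.278 to 19.7 ± 0.695 RPKM and the B-box transcription factor gene BBX20 from 15 ± 1.95 to 31.6 ± 1.42 RPKM. Their adjusted p-values were 0.000472, 0.00039 and 0.000148.

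Smaller changes were called for 3 other genes of these pathways. SMXL6 rose from 7.14 ± 0.357 to 10.4 ± 0.249 RPKM (adjusted p = 0.0306) and the karrikin pathway repressor gene SMAX1 from 77.4 ± 1.26 to 94.5 ± 3.2 RPKM (adjusted p = 0.0281). The receptor gene D14 fell from 71.7 ± 4.52 to 56.9 ± 3.92 RPKM (log2 difference -0.33, adjusted p = 0.0204). These calls did not hold when a library was left out. Those of SMXL6 and SMAX1 ended without any 1 of the 6 libraries of 2 h, at adjusted p of 0.0642 to 0.121 and of 0.0615 to 0.14. That of D14 ended without solvent 2 h replicate 1 (0.0914) or 2 (0.0605) or GR24 4DO 2 h replicate 2 (0.13) or 3 (0.0776). With gene length trends removed, SMAX1 was at 0.336; over its alternatives its adjusted p ran from 0.0104 to 0.336, that of SMXL6 from 0.0126 to 0.164 and that of D14 from 0.00471 to 0.13. In the karrikin list, 5 of 9 genes tested rose (8 when adjusted over the list alone) and 0 fell, with a median log2 difference of 0.28 and a camera adjusted p of 1.8e-09. In the strigolactone list, 3 of 9 rose and 1 fell (5 and 2 adjusted over the list alone). Camera, which compares a list with the other genes, gave an adjusted p of 0.228. Fry, which tests for a change of the list itself, gave 1.1e-05. BRC1, the gene of a transcription factor that holds back bud outgrowth, lay below the expression filter; it is singled out here after its values were seen. It had 1, 1 and 0 reads in solvent and 5, 6 and 5 reads with GR24 4DO, and limma-voom with a wider filter called it at an adjusted p of 0.0269.

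**Figure D1:**
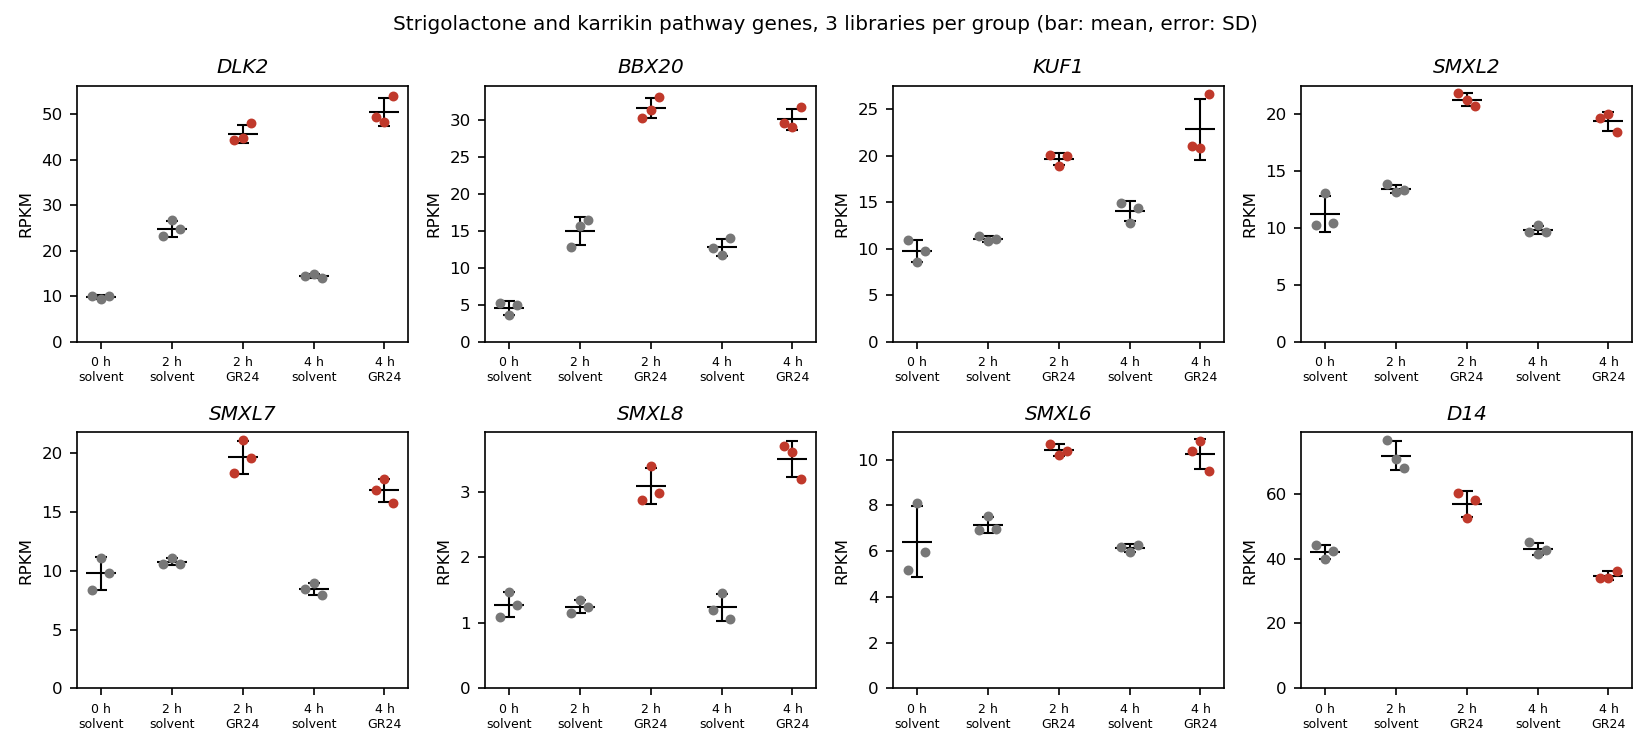
RPKM (vertical axes) of 8 strigolactone and karrikin pathway genes in the 5 groups (horizontal axes). Points are libraries, bars the mean and error bars the SD of 3 libraries; with GR24 4DO, DLK2 stood at 45.7 RPKM at 2 h and 50.6 RPKM at 4 h, and D14 at 56.9 and 34.8 RPKM.

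Outside the signalling genes, the highest log2 difference at 2 h among called genes belonged to AT5G56840, which encodes a MYB-like transcription factor and rose from 1.67 ± 0.192 to 5.51 ± 0.953 RPKM (1.28, SE 0.14). The glutathione S-transferase gene GSTU22 rose from 2.87 ± 0.335 to 8.09 ± 0.702 RPKM and the ABC transporter gene ABCG37 from 4.48 ± 0.748 to 9.72 ± 0.823 RPKM. FRU, which encodes a regulator of iron uptake in roots, rose from 5.41 ± 0.529 to 10.9 ± 1.26 RPKM. The cytokinin signalling genes ARR16 and AHP4 rose from 4.04 ± 0.279 to 8.22 ± 1.11 RPKM and from 2.82 ± 0.182 to 5.94 ± 0.0976 RPKM, and the pectin methylesterase family gene AT5G51500 from 0.66 ± 0.141 to 2.03 ± 0.0263 RPKM. CYP707A3 and CYP707A1, whose enzymes break down abscisic acid, rose by log2 differences of 0.85 and 0.53. Among the lowest differences were AT5G62280, of unknown function, at -0.89 (19.2 ± 1.22 to 9.88 ± 0.131 RPKM) and AT3G21352, also of unknown function, at -0.89 (5.11 ± 0.822 to 2.33 ± 0.731 RPKM). They were followed by the glutaredoxin gene AT3G21460 at -0.87, AT5G12050 at -0.74, and the protein phosphatase gene AT5G02760 at -0.70 (38.9 ± 2.45 to 23.5 ± 1.22 RPKM). All these genes passed the test, with adjusted p-values of 0.000148 to 0.00557. The SAUR-like genes AT1G29450, SAUR29 and AT1G29460 were at -0.78, -0.77 and -0.71 (adjusted p = 0.0179, 0.0179 and 0.00744). The call of AT1G29450 ended without solvent 2 h replicate 1 or 2 or GR24 4DO 2 h replicate 1 or 2 (0.0517 to 0.0988). That of SAUR29 ended without solvent 2 h replicate 1 or GR24 4DO 2 h replicate 2 or 3 (0.0753 to 0.112).

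Auxin-responsive genes were lower with GR24 4DO at 2 h. Of 28 tested, 1 rose and 2 fell, or 1 and 17 when adjusted over the list alone, and the median log2 difference was -0.24 (camera adjusted p = 5.42e-13). IAA29, an auxin-induced repressor gene, fell from 1.29 ± 0.018 to 0.53 ± 0.177 RPKM, and GH3.6, whose enzyme conjugates auxin to amino acids, rose from 14 ± 1.14 to 18.9 ± 0.102 RPKM. Flavonoid and anthocyanin genes were higher, with 4 of 21 risen and 0 fallen (9 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.000121). Of these 4 calls, those of CHS, CHIL and MYB111 each ended without any 1 of several libraries of 2 h, at adjusted p of up to 0.0915, 0.118 and 0.134. FLS1, which encodes flavonol synthase, rose from 20.8 ± 0.405 to 28.0 ± 1.41 RPKM. Together with the karrikin list, these were the 3 lists whose calls at 2 h held with an estimated correlation, at adjusted p of 0.00017 for the auxin, 0.00723 for the flavonoid and 0.000757 for the karrikin genes.

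Another 6 lists passed camera at 2 h and lost the call with an estimated correlation. Light-harvesting genes had 0 risen and 2 fallen of 20 (0 and 14 adjusted over the list alone, median -0.21, camera adjusted p = 8.95e-15), with adjusted p = 0.0559 with an estimated correlation. Both gene calls, LHCB1.4 and LHCB2.3, ended without any 1 of several libraries of 2 h, at adjusted p of up to 0.115 and 0.0922. Ethylene genes had 0 of 17 called (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000218), with adjusted p = 0.0504 with an estimated correlation. In the sugar starvation and dormancy list, ASN1, which encodes an asparagine synthetase, fell from 3.48 ± 0.242 to 2.22 ± 0.259 RPKM, and 2 of 13 members fell (4 adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.0771 with an estimated correlation). Cell cycle genes had 0 of 26 called (3 higher adjusted over the list alone, median 0.16, camera adjusted p = 0.0118, adjusted p = 0.49 with an estimated correlation). Of the xenobiotic detoxification genes, 2 of 23 rose (3 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.213 with an estimated correlation), GSTU25 among them with a log2 difference of 0.49. That call ended without solvent 2 h replicate 2 (0.0705) or 3 (0.159) or GR24 4DO 2 h replicate 1 (0.161), with the 3 near-identical pairs averaged (0.118) and with median-of-ratios scaling (0.057). Of the heat shock genes, 1 of 9 fell (2 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.502 with an estimated correlation). That list call ended with the replicate block (0.0546), quantile normalization (0.0563) and gene length trends removed (0.0509, or 0.0862 with the block). It also ended without solvent 2 h replicate 1 (0.339) or GR24 4DO 2 h replicate 1 (0.161) or 3 (0.0749). Fry, which tests for a change of the list itself, gave 0.422. The call of HSP17.4, the 1 heat shock gene called, ended without any 1 of the 6 libraries of 2 h (0.0661 to 0.212).

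The other 15 lists did not pass camera at 2 h. Genes called in them included PDC1 and HUP7, 2 of 15 hypoxia genes (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.308), at 4.82 ± 0.262 against 7.69 ± 0.414 RPKM and 4.99 ± 0.461 against 7.79 ± 0.241 RPKM. Of 25 abscisic acid genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone, 0.899), among them the cold-induced gene COR15A, from 143 ± 3.9 to 113 ± 5.36 RPKM. ELIP1, which encodes a protein of light stress, rose from 7.55 ± 0.681 to 12.5 ± 1.29 RPKM as 1 of 14 light signalling genes (3 adjusted over the list alone, 0.228). PR2, a defence gene, rose from 15.2 ± 1.25 to 20.5 ± 0.595 RPKM as 1 of 2 called among 16 salicylic acid genes (5 higher and 1 lower adjusted over the list alone, 0.194). Called were also 2 of 14 cytokinin genes (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.824), 1 of 9 gibberellin genes (1 and 1, adjusted p 0.734) and 1 of 24 jasmonate genes (2 and 3, adjusted p 0.228). So were 1 of 7 brassinosteroid genes (2 and 0, adjusted p 0.439), 1 of 18 root cell markers (1 and 0, adjusted p 0.138) and 2 of 17 shoot cell markers (2 and 2, adjusted p 0.741). Other gene calls at 2 h that ended without any 1 of several libraries included AOS, CYP90D1, FAMA, GA3OX2, HAT2, RAB18, SPCH, UGT73B4 and WRKY70. Their highest adjusted p ran from 0.0984 (AOS) to 0.22 (FAMA). The jasmonate list passed without solvent 2 h replicate 1 (0.0166), and the root cell markers without solvent 2 h replicate 2 (0.0433) or 3 (0.0465) and with the 3 near-identical pairs averaged (0.0453). Fry, which tests for a change of the list itself, passed for the hypoxia (0.00143), salicylic acid (0.00652), brassinosteroid (0.022), light signalling (0.0274) and root marker lists (0.0451). It passed for no other of these 15 lists. The early wound and defence list had 0 of 17 genes called (1 higher adjusted over the list alone, 0.824), and the lists of nitrate (12 genes, 0.333), phosphate (14, 0.354), morning-phased clock (12, 0.984) and afternoon- and evening-phased clock genes (10, 0.851) had 0 called either way. For the cytokinin, abscisic acid, jasmonate, phosphate, morning-phased clock and shoot marker lists, median and mean lay above 0 while the test, which compares a list with the other genes, pointed down; the median of all genes was 0.055.

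Of 19155 genes tested with limma, 249 passed at 2 h, 170 higher and 79 lower, and 3510 had an unadjusted p under 0.05. In each of the genes described as risen or fallen, the 3 GR24 4DO libraries lay on 1 side of the 3 solvent libraries. This was a condition for naming the highest and lowest differences, and the others were named for calls or small adjusted p. It therefore adds no evidence for these genes. Over all genes, 26.2% had such groups. Chance gives 10% for 6 independent libraries, and more if a near-identical pair is 1 sample. The split of calls moved with scaling, to 121 higher and 148 lower with quantile normalization and 104 and 100 with median-of-ratios scaling, and to 145 and 141 with gene length trends removed. The pairing by replicate number at 2 h rested on low correlations of residuals and is uncertain. At 4 h the correlations for the same number were -0.183, 0.491 and 0.407. Near-identical pairs in both groups of 4 h shape such correlations, so pairing is undecided there. With the replicate block over all 15 libraries 1025 genes passed, 777 higher and 248 lower. With the block in the 6 libraries of 2 h alone, 262 passed, 190 higher and 72 lower, of which 158 were among the 249, so 91 calls were lost. These included SMAX1 (adjusted p = 0.0557), D14 (0.0502), IAA29 (0.0537) and ASN1 (0.0617). With the 3 near-identical pairs averaged, 67 genes passed. Calls lost there included IAA29 (0.0547), ASN1 (0.0856), ELIP1 (0.0532) and GSTU25 (0.0662). The count fell to 117 without solvent 2 h replicate 1, 126 without replicate 2, 98 without GR24 4DO 2 h replicate 2 and 92 without replicate 3.

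The comparison at 4 h asked how the response had developed. DLK2 now had the highest log2 difference of the genes named by rule, from 14.4 ± 0.36 RPKM in solvent to 50.6 ± 2.97 RPKM with GR24 4DO (n = 3 and 3, log2 difference 1.74, SE 0.06, adjusted p = 1.91e-10). SMXL7 rose from 8.46 ± 0.549 to 16.8 ± 0.98 RPKM, SMXL8 from 1.23 ± 0.207 to 3.49 ± 0.264 RPKM, SMXL6 from 6.14 ± 0.157 to 10.2 ± 0.658 RPKM, and SMXL2 from 9.79 ± 0.334 to 19.3 ± 0.827 RPKM, with adjusted p-values of 1.57e-06 to 0.000823. KUF1 rose from 14.1 ± 1.08 to 22.8 ± 3.26 RPKM and BBX20 from 12.8 ± 1.15 to 30.1 ± 1.41 RPKM. MYB75, which encodes an activator of anthocyanin synthesis, rose from 0.898 ± 0.134 to 2.4 ± 0.148 RPKM (adjusted p = 2.73e-05). D14 fell from 42.9 ± 1.86 to 34.8 ± 1.34 RPKM and LBO, whose enzyme acts late in strigolactone synthesis, from 4.43 ± 0.323 to 3.07 ± 0.12 RPKM. Called with larger adjusted p were SMAX1, from 64.4 ± 4.25 to 80.8 ± 1.23 RPKM (0.00249), its relative SMXL3, from 2.51 ± 0.116 to 3.45 ± 0.163 RPKM (0.0385), and the strigolactone synthesis gene CCD8, from 0.935 ± 0.0787 to 0.517 ± 0.0548 RPKM (0.0172).

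In the karrikin list, 6 of 9 genes rose and 0 fell, also when adjusted over the list alone (median 0.34, camera adjusted p = 3.1e-09). In the strigolactone list, 4 of 9 rose and 3 fell (5 and 4 adjusted over the list alone). Camera gave an adjusted p of 0.179, and of 0.0487 with gene length trends removed and 0.049 with 3 near-identical pairs averaged. Fry, which tests for a change of the list itself, gave 1.25e-06. The call of D14 ended without solvent 4 h replicate 1 (0.0583) or GR24 4DO 4 h replicate 1 (0.0513). That of CCD8 ended without solvent 4 h replicate 1 (0.0835) or 3 (0.0564) or GR24 4DO 4 h replicate 1 (0.0799) or 2 (0.0658), and that of SMXL3 without any 1 of the 6 libraries of 4 h (0.0502 to 0.14). With gene length trends removed, SMAX1 was at 0.191 (0.00112 to 0.191 over its alternatives) and SMXL3 at 0.0522 (0.0132 to 0.315). With the 3 near-identical pairs averaged, D14 was at an adjusted p of 0.184 (0.00259 to 0.184 over its alternatives), LBO at 0.0564 (0.000444 to 0.0564) and CCD8 at 0.22 (0.00453 to 0.22). The reads of BRC1, again singled out after its values were seen, numbered 2, 1 and 1 in solvent and 8, 10 and 12 with GR24 4DO, and limma-voom with a wider filter called it at an adjusted p of 0.00748. Of the other list members below the filter, that fit also called HB40 of the strigolactone list (0.0263), GA2OX1 of the gibberellin list (0.0131) and JMT of the jasmonate list (0.00327), all higher.

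Genes for the detoxification of foreign compounds rose at 4 h. Of 23 tested, 12 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 difference of 0.46 (camera adjusted p = 5e-10). The oxophytodienoate reductase genes OPR1 and OPR2 rose from 89.9 ± 3.37 to 162 ± 4.64 RPKM and from 19.6 ± 2.26 to 37.8 ± 2.4 RPKM. The glycosyltransferase gene UGT73B4 rose from 11 ± 0.431 to 21.2 ± 0.592 RPKM and GSTU25 from 22.8 ± 1.61 to 43.7 ± 1.3 RPKM, with adjusted p-values of 5.1e-07 and 1.6e-06. Flavonoid and anthocyanin genes rose as well, 9 of 21 with 0 fallen (15 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 5e-10). Examples were TT7, which encodes flavonoid hydroxylase (3.59 ± 0.318 to 6.78 ± 0.355 RPKM), CHS, which encodes chalcone synthase (log2 difference 0.44, from 236 to 319 RPKM), and FLS1 (39.3 ± 1.52 to 55.5 ± 1.9 RPKM). In the sugar starvation and dormancy list, 5 of 13 rose (7 higher and 1 lower adjusted over the list alone, median 0.25, camera adjusted p = 0.000382), among them DIN10, from 75.8 ± 1.32 to 105 ± 3.63 RPKM, and TPS11, from 3.41 ± 0.479 to 5.73 ± 0.697 RPKM.

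Auxin-responsive genes fell, 9 of 28 with 1 risen (15 lower and 1 higher adjusted over the list alone, median -0.23, camera adjusted p = 7.2e-10). The auxin repressor genes IAA19, IAA5 and IAA7 fell from 6.5 ± 0.14 to 2.93 ± 0.168 RPKM, from 1.4 ± 0.233 to 0.395 ± 0.133 RPKM and from 53.5 ± 0.0916 to 39.6 ± 0.536 RPKM. Hypoxia genes fell, 5 of 15 with 1 risen (7 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 0.000108). PGB1, which encodes a phytoglobin, fell with a log2 difference of -0.70 from 33.4 ± 0.883 RPKM, the alcohol dehydrogenase gene ADH1 from 17 ± 1.31 to 11 ± 0.395 RPKM, and HUP7 from 10.1 ± 0.647 to 5.79 ± 0.642 RPKM. In the ethylene list 4 of 17 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 0.00048). ARGOS, which dampens ethylene responses, fell from 26.7 ± 1.02 to 14.3 ± 0.149 RPKM and the receptor gene ETR2 from 14.8 ± 0.064 to 8.96 ± 0.0421 RPKM. At 4 h 7 lists held with an estimated correlation, at adjusted p of 0.000599 for karrikin, 0.00035 for flavonoid, 0.00035 for auxin, 0.00182 for xenobiotic detoxification, 0.0054 for hypoxia, and 0.0416 for both the sugar starvation and the ethylene genes. The salicylic acid genes lost the call, with 3 of 16 fallen (4 adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.0994 with an estimated correlation). So did the afternoon- and evening-phased clock genes, with 4 of 10 risen (5 adjusted over the list alone, 0.0116, adjusted p = 0.0994 with an estimated correlation). WRKY38 fell from 2.11 ± 0.193 to 0.795 ± 0.209 RPKM, ICS1, which encodes a salicylic acid synthesis enzyme, from 8.2 ± 0.0503 to 5.73 ± 0.168 RPKM, and the clock gene PRR5 rose from 7.56 ± 0.231 to 11.4 ± 0.263 RPKM.

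Several single genes changed by more than most list members at 4 h. AT3G25190, of the vacuolar iron transporter family, rose from 3.55 ± 0.533 to 11.9 ± 0.821 RPKM, and AT5G56840 from 1.8 ± 0.137 to 6.69 ± 0.192 RPKM. The beta-glucosidase gene BGLU47 rose from 0.747 ± 0.23 to 3.26 ± 0.805 RPKM and ARR16 from 5.86 ± 0.166 to 15.6 ± 0.416 RPKM. AT2G22590, which encodes a glycosyltransferase, rose from 0.525 ± 0.0442 to 2.67 ± 0.123 RPKM, AT1G30250, of unknown function, from 0.283 ± 0.0663 to 2.15 ± 0.133 RPKM, and ABCG37 from 3.93 ± 0.118 to 10.4 ± 0.938 RPKM. The lowest log2 differences were those of the dirigent gene DIR5 at -1.32 (14.7 ± 1.7 to 5.26 ± 0.486 RPKM), the chitinase family gene AT2G43620 at -1.23 (172 ± 1.8 to 72.7 ± 8.28 RPKM) and AT5G62280 at -1.21 (12.2 ± 1.35 to 4.7 ± 0.716 RPKM). They were followed by the peroxidase gene AT5G19890 at -1.16 (44.1 ± 4.35 to 19.3 ± 1.9 RPKM), the homeobox gene HB52 at -1.08, the SAUR-like gene AT5G20820 at -1.08, the lipid transfer family gene AT4G22470 at -1.07 and AT3G21352 at -1.06. Adjusted p-values ran from 6.91e-08 to 0.00067.

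Besides the strigolactone list, 15 lists did not pass camera at 4 h. Several held members that moved apart. In the jasmonate list 6 of 24 rose and 3 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.953). LOX4, a synthesis gene, rose from 5.17 ± 0.365 to 8.38 ± 0.242 RPKM, while ST2A and CYP94C1, whose enzymes inactivate jasmonates, fell from 28.6 ± 1.49 to 13.5 ± 0.892 RPKM and from 17.7 ± 0.538 to 12.5 ± 0.36 RPKM. In the abscisic acid list 3 of 25 rose and 5 fell (4 and 6 adjusted over the list alone, 0.688), with CYP707A3 at 2.47 ± 0.21 against 5.69 ± 0.6 RPKM and COR15A at 90.7 ± 2.04 against 51.3 ± 1.92 RPKM. In the light signalling list 4 of 14 rose and 1 fell (5 and 3, adjusted p 0.294), ELIP1 from 6.92 ± 0.471 to 14.5 ± 0.558 RPKM and PIF3, the gene of a growth-promoting factor degraded in light, from 15.2 ± 0.519 to 9.95 ± 0.697 RPKM. Of 9 gibberellin genes 1 rose and 1 fell (2 and 1, adjusted p 0.371), and GA3OX2, a synthesis gene, rose from 3.28 ± 0.198 to 6.65 ± 0.234 RPKM. Of 12 nitrate genes 2 rose and 2 fell (3 and 4, adjusted p 0.908), and the transporter gene NRT2.1 rose from 74.5 ± 8.95 to 121 ± 4.57 RPKM. Of 14 phosphate starvation genes 0 rose and 3 fell (0 and 3, adjusted p 0.144), and RNS1, which encodes a ribonuclease, fell from 38.1 ± 0.747 to 19.9 ± 1.35 RPKM. Of 17 wound and defence genes 5 rose and 2 fell (7 and 3, adjusted p 0.27), WRKY33 from 42.5 ± 0.819 to 60.2 ± 3.34 RPKM and WRKY22 from 11.1 ± 0.243 to 7.24 ± 0.735 RPKM; with gene length trends removed this list was at 0.0487. In the cytokinin list 2 of 14 rose and 1 fell (4 and 2, adjusted p 0.908), and in the brassinosteroid list 1 of 7 rose (1 and 0, adjusted p 0.454). In the morning-phased clock list 1 of 12 rose (1 and 0, adjusted p 0.0712, 0.0439 without GR24 4DO 4 h replicate 2 and 0.0354 with median-of-ratios scaling). In the light-harvesting list 2 of 20 rose (3 and 0, adjusted p 0.836), and in the heat shock list 1 of 9 (1 and 0, adjusted p 0.27). Of the cell cycle genes 0 of 26 were called (0 and 0, adjusted p 0.27). Of the root cell markers 1 of 18 fell (0 and 1, adjusted p 0.575), and of the shoot cell markers 1 of 17 rose and 1 fell (2 and 2, adjusted p 0.656). The pairs in parentheses are counts higher and lower adjusted over the list alone. Gene calls at 4 h that ended without any 1 of several libraries included CYP90D1, FKF1, GID1C, HY5, LHCA6, PHT1.4, RFNR1, RSL4 and TOC1. Their highest adjusted p ran from 0.0747 (TOC1) to 0.167 (CYP90D1). Fry, which tests for a change of the list itself, passed for the phosphate (1.81e-05), gibberellin (0.0126), wound and defence (0.0163), morning-phased clock (0.0291) and light signalling lists (0.0382). Median and mean differed in sign in the cytokinin, abscisic acid, nitrate, phosphate and root marker lists.

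At 4 h, limma called 1710 genes, 899 higher and 811 lower. Over all genes, 33.5% had groups that did not overlap, and these included each gene named here as risen or fallen. Chance gives 10% for independent libraries, and more if the libraries of a near-identical pair are not separate samples. Both groups of 4 h held such a pair, so the excess over 10% does not by itself show a response. The count was 938 with solvent 4 h replicates 1 and 3 averaged into 1 sample and 464 with the 3 near-identical pairs averaged. With gene length trends removed, 1638 genes were called, 924 higher and 714 lower, and 369 of the 1710 calls were lost. The median length of called genes was 1665 bp for higher and 1123 bp for lower genes. The count was 935 without solvent 4 h replicate 1, 960 without replicate 3, 920 without GR24 4DO 4 h replicate 1 and 895 without replicate 2.

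**Figure D2:**
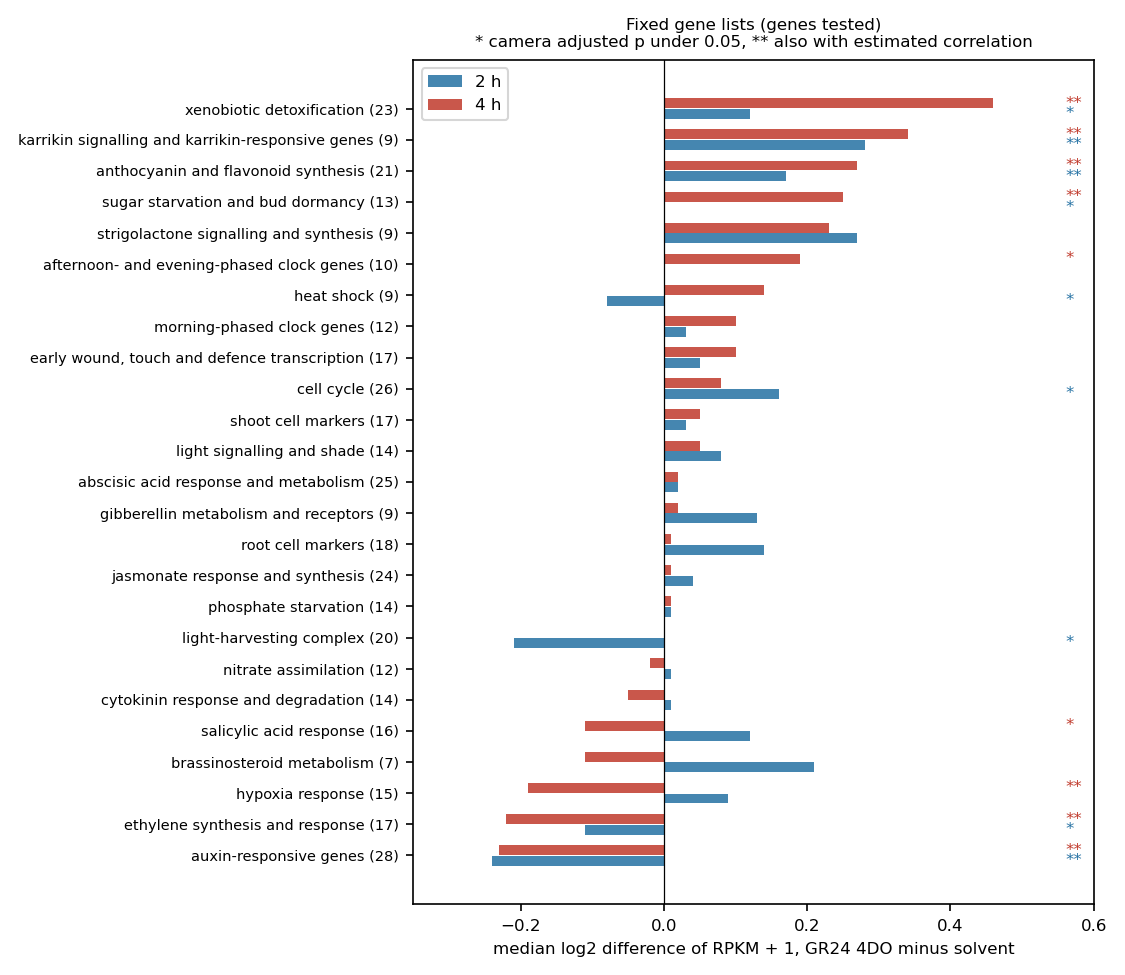
Median log2 difference between GR24 4DO and solvent (horizontal axis, RPKM + 1 scale) for each of 25 gene lists fixed in advance (vertical axis, genes tested in brackets) at 2 h and 4 h. Xenobiotic detoxification had the highest median at 4 h, 0.46, and the auxin list stood at -0.24 at 2 h and -0.23 at 4 h.

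The genes called at 2 h and at 4 h were compared directly. Of 170 genes higher at 2 h, 111 were also higher at 4 h, where 7.98 would be shared by independent lists (Fisher's exact test, one-sided p = 9.83e-106). Of 79 genes lower at 2 h, 46 were also lower at 4 h, against 3.34 (Fisher's exact test, one-sided p = 9.72e-43). Another 5 genes were called at both times in opposite directions, HUP7 among them. DLK2, SMXL7, SMXL8, SMXL2, KUF1, BBX20, ABCG37, ARR16 and AT5G56840 were higher, and D14, AT5G62280, AT3G21352 and COR15A lower, at both times. Across all genes the log2 differences of both times correlated with Pearson's r of 0.47 and Spearman's rho of 0.47, and 224 of the 249 genes called at 2 h had the same sign at 4 h. Genes are not independent replicates. The comparisons shared no library, but they came from 1 fit and shared each gene's variance estimate, so their calls are not independent. Counted in the same direction, 157 genes were called at both times. The number was 417 with the replicate block, 46 with the 3 near-identical pairs averaged, 92 without solvent 2 h replicate 1 or replicate 2, 75 without GR24 4DO 2 h replicate 2 and 69 without replicate 3.

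**Figure D3:**
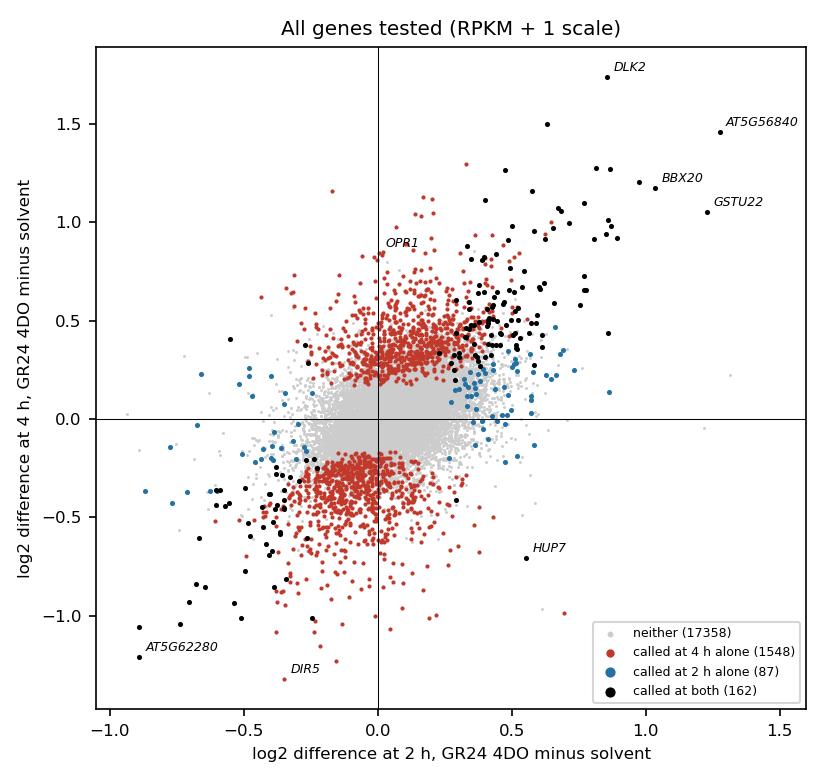
Log2 difference between GR24 4DO and solvent at 2 h (horizontal axis) and at 4 h (vertical axis), both on the RPKM + 1 scale, for 19155 genes. Of these, 162 were called at both times, 87 at 2 h alone and 1548 at 4 h alone, and DLK2 lies at 0.86 and 1.74.

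The response itself was tested for a difference between 4 h and 2 h. CYP81D11, a detoxification cytochrome P450 gene, stood at 30.2 ± 0.926 RPKM in solvent and 26.7 ± 0.749 RPKM with GR24 4DO at 2 h. At 4 h it stood at 10.6 ± 0.765 and 24.9 ± 1.64 RPKM (n = 3 per group, difference of log2 differences 1.33, SE 0.09, adjusted p = 2.62e-06). The response of OPR1 differed by 0.84 (182 and 182 RPKM at 2 h, 89.9 and 162 RPKM at 4 h), that of the glycosyltransferase gene UGT73B2 by 0.84 (54.6 and 63.0 RPKM, then 34.5 and 72.5 RPKM), that of AT5G61820 by 0.90 and that of DLK2 by 0.88. In the other direction, HUP7 differed by -1.26, AT2G43620 by -1.08 (147 and 132 RPKM, then 172 and 72.7 RPKM), the peroxidase genes AT5G39580 and AT1G49570 by -0.99 (53.7 and 53.3 RPKM, then 58.5 and 28.7 RPKM) and -0.77, and AT1G80130 by -0.85. Adjusted p-values for these 10 genes were at most 0.000211.

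Among the lists, the response of xenobiotic detoxification genes was higher at 4 h than at 2 h, with 9 of 23 genes called higher and 1 lower (12 and 3 adjusted over the list alone, camera adjusted p = 6e-10). The sugar starvation list was higher, with 4 of 13 called (8 adjusted over the list alone, 7.64e-11), and so was the flavonoid list, with 1 of 21 called (2 higher and 1 lower adjusted over the list alone, 0.000186). The hypoxia list was lower, with 3 of 15 called (8 adjusted over the list alone, 3.77e-07), and so was the salicylic acid list, with 1 of 16 called (8 adjusted over the list alone, 9.42e-06). These 5 held with an estimated correlation, at adjusted p of 0.00286, 0.00286, 0.00745, 0.00286 and 0.0127. Another 5 lists lost the call. Light-harvesting genes were higher with 3 of 20 called (7 adjusted over the list alone, 7.64e-11, adjusted p = 0.0782 with an estimated correlation). Heat shock genes were higher with 0 of 9 called (1 adjusted over the list alone, 7e-04, adjusted p = 0.314 with an estimated correlation). Evening-phased clock genes were higher with 0 of 10 called (3 adjusted over the list alone, 0.00113, adjusted p = 0.0539 with an estimated correlation). Karrikin genes were higher with 1 of 9 called (1 adjusted over the list alone, 0.0235, adjusted p = 0.0749 with an estimated correlation). Root cell markers were lower with 0 of 18 called (1 adjusted over the list alone, 0.0407, adjusted p = 0.394 with an estimated correlation). The karrikin call ended without solvent 4 h replicate 2 (0.0741) or GR24 4DO 4 h replicate 3 (0.0672), and with gene length trends removed (0.0651, or 0.0665 with the replicate block). The root marker call ended without solvent 2 h replicate 1 (0.279), solvent 4 h replicate 1 (0.0699) or 3 (0.0998), GR24 4DO 2 h replicate 3 (0.0998), or GR24 4DO 4 h replicate 1 (0.0953) or 2 (0.0729). It also ended with gene length trends removed (0.0651, or 0.0501 with the block). Fry, which tests for a change of the list itself, gave 0.106 for the root markers and 0.205 for the heat shock genes. The morning-phased clock list passed without GR24 4DO 2 h replicate 3 (0.047).

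The response of 329 genes differed between the times in limma, 184 higher at 4 h and 145 lower. The split was 218 and 113 with quantile normalization, 192 and 102 with median-of-ratios scaling and 278 and 118 with gene length trends removed. The count was 51 with the 3 near-identical pairs averaged. It was 211 without solvent 4 h replicate 1 and 203 without replicate 3, 212 without GR24 4DO 2 h replicate 2 and 209 without replicate 3, and 199 without GR24 4DO 4 h replicate 1 and 216 without replicate 2.

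The solvent groups show how transcripts moved over the time points without GR24 4DO, against which its effects were measured. The hour of the day may have advanced with time in culture, and the design cannot separate them. Light-harvesting genes fell steeply. All 20 were lower at 2 h than at 0 h and all 20 at 4 h, also when adjusted over the list alone, with median log2 differences of -1.11 and -2.45 (camera adjusted p = 1.38e-34 and 6.86e-32). LHCB2.1, which encodes an antenna protein of photosystem II, went from 1830 ± 242 RPKM at 0 h to 346 ± 29.1 RPKM at 2 h and 63.1 ± 2.54 RPKM at 4 h (n = 3 each). Morning-phased genes were lower at 2 h (9 of 12 fallen and 1 risen, median -0.87, camera adjusted p = 1.41e-08) and at 4 h (10 fallen and 1 risen, median -1.31, 9.76e-09). Of 10 afternoon- and evening-phased genes, 9 were higher at 2 h (median 1.1, 9.69e-10), and 7 were higher and 2 lower at 4 h (median 0.80, 0.00571, but adjusted p = 0.0729 with an estimated correlation). Adjusted over the list alone, these counts were the same but for 8 higher in the last. ELF4 went from 18.1 ± 1.26 RPKM to 75.1 ± 3.42 and 94.9 ± 3.66 RPKM, and LNK2 from 16.4 ± 2.35 RPKM to 3.71 ± 0.586 and 0.851 ± 0.172 RPKM. JMJD5, a clock-associated gene, went from 1.73 RPKM to 18.3 and 46.8 RPKM and AT1G07050, of the CCT motif family, from 3.75 RPKM to 50.4 and 52.1 RPKM.

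Sugar starvation genes were lower at 2 h (6 of 13 fallen, median -0.19, camera adjusted p = 8.19e-05) and at 4 h (13 of 13 fallen, median -1.02, 6.19e-14), with ASN1 at 9.98, 3.48 and 0.931 RPKM and SEN1 at 37.3, 10.9 and 3.77 RPKM. Adjusted over the list alone, 1 rose and 6 fell at 2 h and 13 fell at 4 h. Auxin-responsive genes were lower at both times, 16 of 28 fallen at 2 h (17 lower and 1 higher adjusted over the list alone, median -0.32, 5.37e-10) and 19 fallen with 1 risen at 4 h (19 and 1, median -0.66, 2.81e-10). Ethylene genes had 12 of 17 fallen at 2 h and 13 at 4 h, the same adjusted over the list alone (1.81e-08 and 6.48e-07). Flavonoid genes had 9 of 21 risen at 2 h (9 adjusted over the list alone, 0.00706) and 13 risen with 1 fallen at 4 h (15 and 1, adjusted p 1.28e-05), CHS at 76.7, 111 and 236 RPKM. Genes of wound and defence were lower, with 9 of 17 fallen and 2 risen at 2 h (9 and 3 adjusted over the list alone, 0.00137) and 10 fallen and 2 risen at 4 h (12 and 3, adjusted p 0.000817). Phosphate starvation genes were higher, with 8 of 14 risen and 1 fallen at 2 h (9 and 1 adjusted over the list alone, 0.0134) and 9 risen and 2 fallen at 4 h (9 and 2, adjusted p 0.00571). Xenobiotic detoxification genes were lower, with 5 of 23 fallen and 2 risen at 2 h (6 and 2 adjusted over the list alone, 0.0285, adjusted p = 0.131 with an estimated correlation) and 12 fallen and 4 risen at 4 h (13 and 4, adjusted p 0.000175, and 0.0248 with an estimated correlation). The 2 h call of that list ended without solvent 0 h replicate 1 (0.0933) or solvent 2 h replicate 2 (0.0512) or 3 (0.0779), with the 3 near-identical pairs averaged (0.0569) and with gene length trends removed with the replicate block (0.0525). DLK2 itself went from 9.85 ± 0.399 RPKM at 0 h to 24.8 RPKM at 2 h and 14.4 RPKM at 4 h in solvent.

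Passing at 2 h were also the karrikin list, with 5 of 9 risen (6 adjusted over the list alone, camera adjusted p = 0.00173), and the gibberellin list, with 7 of 9 risen (7 adjusted over the list alone, 0.0019). So did the jasmonate list, with 16 of 24 risen and 1 fallen (17 and 1 adjusted over the list alone, 5.46e-05), and the nitrate list, with 1 of 12 risen and 7 fallen (1 and 7 adjusted over the list alone, 0.000506). All 4 held with an estimated correlation. Light signalling (2 of 14 risen and 5 fallen, 2 and 7 adjusted over the list alone, 0.0102) was lost at adjusted p = 0.131 with an estimated correlation, and without solvent 2 h replicate 1 (0.0577). Heat shock (6 of 9 risen, 6 and 1 fallen adjusted over the list alone, 0.00148) was lost at adjusted p = 0.217 with an estimated correlation. At 4 h the jasmonate list passed with 15 of 24 risen and 2 fallen (17 and 2 adjusted over the list alone, 0.00571, adjusted p = 0.15 with an estimated correlation). The light signalling list passed with 2 of 14 risen and 6 fallen, the same adjusted over the list alone (0.00571, adjusted p = 0.126 with an estimated correlation). With 13 lists at 2 h and 9 at 4 h, the other calls of the solvent groups held with an estimated correlation. The root cell markers at 2 h (0.0571) passed with the 3 near-identical pairs averaged (0.0206), with the replicate block (0.0425) and without solvent 0 h replicate 2 (0.0231) or solvent 2 h replicate 2 (0.0217) or 3 (0.0213). The hypoxia list at 2 h (0.0798) passed without solvent 0 h replicate 2 (0.0488), and the karrikin list at 4 h (0.0714) with gene length trends removed (0.0301, or 0.0241 with the block).

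From 0 h to 2 h in solvent, limma called 5494 genes, 3644 higher and 1850 lower, and from 0 h to 4 h 8446 genes, 5489 higher and 2957 lower. Groups did not overlap for 36.5% and 50% of genes. Chance gives 10% for independent libraries, and more if the libraries of a near-identical pair are not separate samples. Solvent at 2 h and solvent at 4 h each held such a pair. The splits were 2563 and 2538 and then 4319 and 3928 with quantile normalization, 2176 and 2628 and then 4105 and 4116 with median-of-ratios scaling, and 2468 and 2783 and then 4270 and 4436 with gene length trends removed. With the 3 near-identical pairs averaged, 3442 genes were called at 2 h, and with only the compared groups in the fit 3431.

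**Figure D4:**
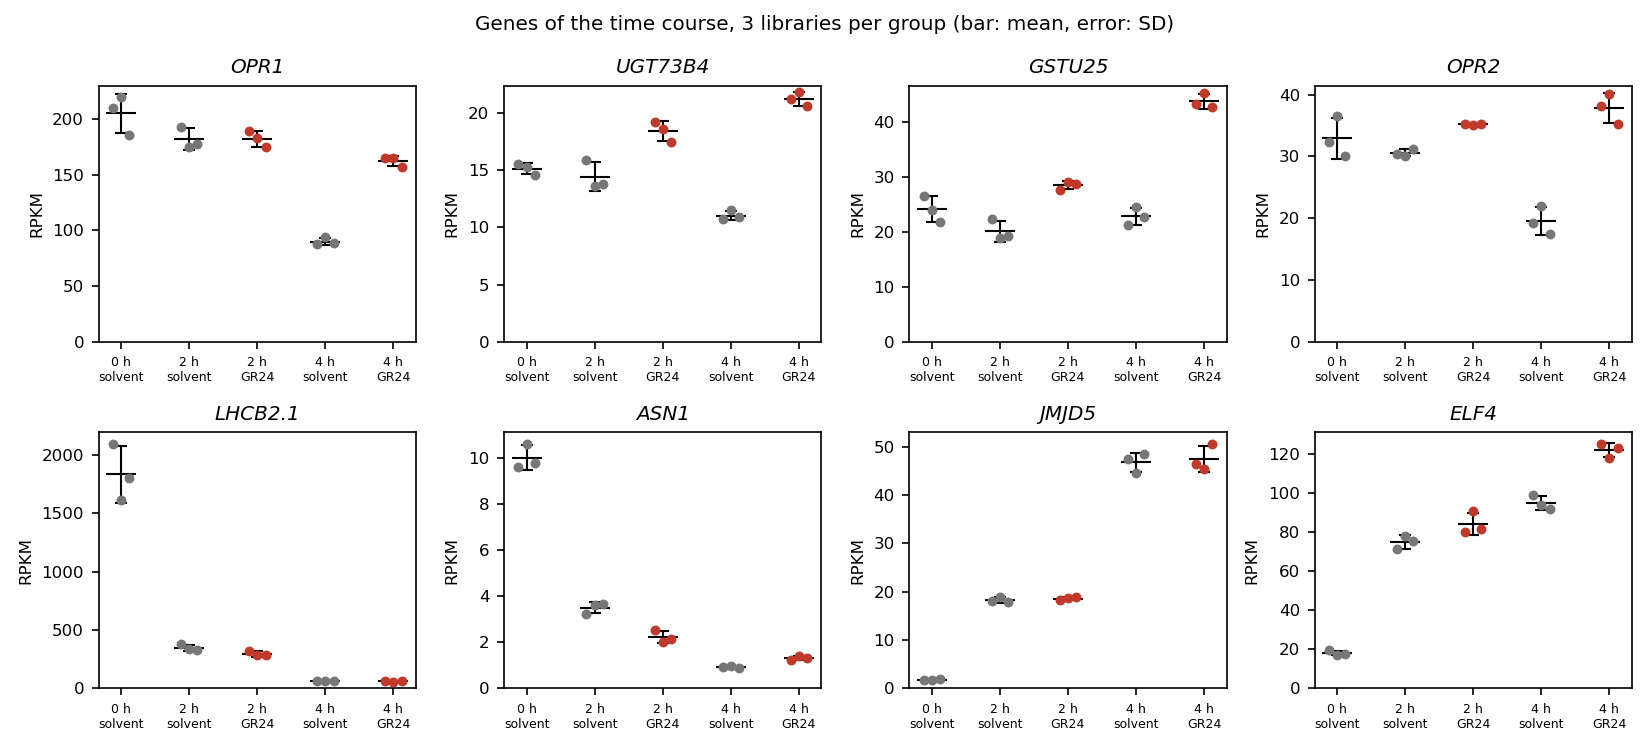
RPKM (vertical axes) of 8 genes in the 5 groups (horizontal axes), with points for libraries, bars for the mean and error bars for the SD of 3 libraries. OPR1 stood at 89.9 RPKM in solvent and 162 RPKM with GR24 4DO at 4 h, against 182 RPKM in both groups at 2 h.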

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

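The tests of the length trend on the counts, of the scale, of the near-identical pair, of the sampling time and of averaged pairs, and the reassignment of residuals, were chosen after the results were seen. What marks the results of this part is that the response to GR24 4DO differed between 2 h and 4 h in a test of that difference, which called 329 genes.

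Among the genes named in the text, which are not all those that differed, CYP81D11 had a higher response at 4 h by 1.33 in log2 units. So had AT1G30250 (0.97), AT5G61820 (0.90), DLK2 (0.88), AT3G25190 (0.87), UGT73B2 (0.84) and OPR1 (0.84). AT2G22590 (0.79), GSTU11 (0.79), ASN1 (0.74), OPR2 (0.72), NRT2.1 (0.71), UGT73B1 (0.71), TT7 (0.62), DIN10 (0.59), LOX4 (0.56) and UGT73B4 (0.55) also had a higher response at 4 h. Lower at 4 h were HUP7 (-1.26), AT4G22470 (-1.11), AT2G43620 (-1.08), AT5G39580 (-0.99), DIR5 (-0.97), AT5G19890 (-0.94) and XTH13 (-0.91). So were AT1G80130 (-0.85), HB52 (-0.84), ADH1 (-0.82), ARGOS (-0.82), RNS1 (-0.80), ST2A (-0.79), AT1G49570 (-0.77), AHP4 (-0.73) and AT5G20820 (-0.70). PGB1 (-0.58), PR2 (-0.52), COR15A (-0.47) and ETR2 (-0.47) followed. Camera adjusted p-values for the difference were 7.64e-11 for the sugar starvation and the light-harvesting genes, 6e-10 for xenobiotic detoxification, 3.77e-07 for hypoxia, 9.42e-06 for salicylic acid, 0.000186 for flavonoid, 7e-04 for heat shock, 0.00113 for evening-phased clock, 0.0235 for karrikin and 0.0407 for root marker genes. With an estimated correlation the calls of 5 of these lists were lost: light-harvesting (0.0782), heat shock (0.314), evening-phased clock (0.0539), karrikin (0.0749) and root marker genes (0.394).

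Other splits of the libraries were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called the most genes, 1 of 10 in each case: 249 at 2 h (highest other 0), 1710 at 4 h (148), 5494 from 0 h to 2 h in solvent (768) and 8446 from 0 h to 4 h (0). For the difference of responses, 8 of 100 drawn splits with labels exchanged within each time called at least as many genes as the real 329, and the highest other called 2485. At the limit of 5 of 100 set before the result was seen, this test came out for chance. The high counts point to the structure of the samples, since 6 of the 7 others kept or exchanged all labels of 4 h and so carried a response to treatment. Of 75 splits that did neither at either time, the highest called 172. In a test chosen after that result, with the additive effects of treatment and time removed, 1 of 100 reassignments of residuals, the real one, called as many, and the highest other called 3. That test takes the residuals as exchangeable. The near-identical pairs within groups contradict this, and a pairing at 2 h would too, so it leaves chance open.

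More genes were higher than lower at 2 h, 170 against 79. With the trend of each library with gene length removed, 50.7% of the called genes were higher, and with quantile normalization 45%, but both settings also bring the median difference of all genes, 0.055, to near 0. Centring moves the shares of higher and lower calls toward even whatever made the shift, so these tests do not tell the length trend, a shift in scale or a wider induction by GR24 4DO apart. Log2 differences rose with gene length, with a Spearman rho of 0.29 at 2 h and 0.37 at 4 h. The length trend does not account for most calls, as 207 of 249 stayed called in the same direction without it at 2 h, and 1341 of 1710 at 4 h, where 369 were lost.

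Solvent 4 h replicates 1 and 3 were nearly identical. The same reads in both columns are excluded by a chi-square of 1.13 per degree of freedom, where the same reads would leave a value near 0. Libraries made from 1 RNA sample cannot be told apart from closely matched cultures, since the CV beyond sampling was 0.8% and no pair of known origin was available. If they were 1 sample, p-values of all contrasts may be too small, since all came from 1 fit. With the pair averaged, 938 genes were called at 4 h, 211 at 2 h and 206 for the difference of responses. In solvent, 7263 genes were called from 0 h to 4 h with the pair averaged. No biological explanation was tested.

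Xenobiotic detoxification genes were higher with GR24 4DO at 4 h, while they fell in solvent. Treated libraries taken earlier than solvent libraries would have raised the light-harvesting genes in the same proportion, but their slope of treated difference on the solvent change was -0.08 (SE 0.04) against 0.71 (SE 0.15) for the xenobiotic genes. Both axes hold the solvent 4 h libraries, whose noise alone gives a slope near 0.01 and 0.04, and with separate libraries on each axis the slopes were -0.09 both ways against 0.59 (SE 0.15) and 0.71 (SE 0.18). The length trend does not account for the call either, at a camera adjusted p of 6.28e-12 without it. With the near-identical pairs averaged, the camera adjusted p was 3.8e-12. Camera at a preset correlation compares genes with genes and depends little on the number of samples. This value therefore cannot decide whether near-identical libraries counted as separate samples made the call. A response of these genes to GR24 4DO or to the compound as a foreign chemical stays open as a hypothesis, and the design cannot separate them.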

How the results depend on the processing

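The settings of averaged pairs, limma-voom, median-of-ratios scaling, length trend and the block in 2 h libraries alone were chosen after the results were seen. The others were set in advance, and those set for read counts were not run. Of the alternatives of named genes, 5494 kept their side of the threshold, 261 lost a call and 90 gained one. Of list tests 1803 kept their side, 52 lost and 45 gained a call. Those kept include changes of direction where neither fit made a call. No direction reversed where either fit made a call, but directions were not compared for fry and the estimated correlation. Of the 8446 calls from 0 h to 4 h in solvent, 1 reversed with quantile normalization. Counts of genes changed more, and the cause was not tested unless fewer samples or a fold limit set it. With only the compared groups, 114 genes were called at 2 h, 3431 from 0 h to 2 h and 80 at both 2 h and 4 h. With the replicate block these were 1025 at 2 h, 2747 at 4 h, 466 for the difference of responses (234 higher and 232 lower) and 417 at both; apart from the values given in the report, the block over all libraries changed no other call named for 2 h. In the 2 h libraries alone it called 262 and kept 158 of the 249 genes. With at least a 2-fold change, 3 genes were left at 2 h, 38 at 4 h, 14 for the difference of responses, 170 and 541 in solvent, and 3 at both. With 3 near-identical pairs averaged, these were 67 at 2 h, 464 at 4 h, 51 for the difference, 3442 from 0 h to 2 h and 46 at both; with solvent 4 h replicates 1 and 3 averaged, 938 at 4 h and 206 for the difference. With the length trend removed and the replicate block, 862 were called at 2 h, 641 for the difference and 376 at both. With limma-voom, 237, 1758, 297, 5678 and 8418 were called in the 5 contrasts. Leaving out 1 library gave 92 to 321 genes at 2 h, 895 to 1694 at 4 h, 199 to 330 for the difference and 69 to 154 at both; 73 genes at 2 h and 744 at 4 h were called in every such fit. List tests passed for 3 lists at 2 h and 5 for the difference with an estimated correlation, and with fry for 14 at 2 h, 15 at 4 h and 19 from 0 h to 4 h in solvent. Depth limits genes below the filter: 1 read in a 1 kb gene was 0.0267 to 0.0409 RPKM.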

Other observations

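The gene families and the test of xenobiotic levels in this part were chosen after the results were seen; the test of the daily course was written before. Families were taken from the reference's gene descriptions, 18 in all, and adjusted p-values are camera's over families. Of the 18, 9 passed camera at 2 h and 11 at 4 h, but 1 at each time with an estimated correlation, the SAUR-like genes at 2 h and the glycosyltransferases at 4 h. With the length trend removed, 4 of the 9 and 4 of the 11 still passed camera in the same direction. Families not described below had adjusted p-values as low as 0.000113 at 2 h and 2.67e-05 at 4 h (cytosolic ribosomal proteins) and lost the call with an estimated correlation. SAUR-like genes, short genes induced by auxin, were lower with GR24 4DO at 2 h, with 5 of 58 fallen and 0 risen (median log2 difference -0.17, adjusted p = 6.75e-15, and 0.00663 with an estimated correlation). SAUR26 went from 1.66 ± 0.171 to 0.727 ± 0.202 RPKM. The family stayed lower with quantile normalization (8.75e-13) and with the length trend removed (4.07e-07). At 4 h 8 fell and 1 rose (0.000192, but adjusted p = 0.222 with an estimated correlation and 0.104 with the length trend removed). Copies of these genes are alike, so reads may have been shared among them.

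Glycosyltransferase genes were higher at 4 h, with 23 of 109 risen and 4 fallen (median 0.06, adjusted p = 0.00108, and 0.0347 with an estimated correlation). With the length trend removed the adjusted p was 0.0045, and 0.681 with an estimated correlation, so that call was lost. UGT73B1 rose from 22.5 ± 0.693 to 49.9 ± 2.23 RPKM and UGT73B2 from 34.5 ± 1.18 to 72.5 ± 3.55 RPKM. Glutathione S-transferase genes had 12 of 48 risen and 3 fallen (0.00454, adjusted p = 0.559 with an estimated correlation), with GSTU11 at 6.53 ± 0.307 against 13 ± 0.554 RPKM. Class III peroxidase genes had 14 of 66 fallen and 3 risen (0.000133, adjusted p = 0.327 with an estimated correlation), AT1G49570 from 29.8 ± 0.766 to 14.3 ± 0.592 RPKM. Wall-modifying xyloglucan endotransglucosylase genes had 7 of 25 fallen and 3 risen (0.00327, adjusted p = 0.279 with an estimated correlation), XTH13 from 23.5 ± 0.245 to 13.3 ± 1.82 RPKM. With the length trend removed, adjusted p-values were 3.74e-05 for the transferase, 0.00451 for the peroxidase and 0.111 for the endotransglucosylase genes.

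A first hypothesis was that GR24 4DO keeps xenobiotic detoxification genes near their level at 0 h while they fall in solvent. The median log2 difference from solvent at 0 h was 0.15 with GR24 4DO at 4 h and -0.35 in solvent at 4 h. Of 23 members, 9 were called higher than at 0 h and 8 lower. A median near 0 over members that go both ways decides nothing, so the hypothesis stays open.

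A second hypothesis was that GR24 4DO moves seedlings ahead along the daily course. The GR24 4DO difference at 2 h was set against the solvent change from 0 h to 4 h. Its slope was -0.03 (SE 0.02) across 22 clock genes and 0.02 (SE 0.01) across 20 light-harvesting genes. Over all 19155 genes the correlation was 0.16 (Spearman's rho 0.11). The clock slope argues against the hypothesis for the clock genes at 2 h alone. The fits held an intercept, so a shift of a whole list does not show in the slopes. Light-harvesting genes were lower at 2 h (median log2 difference -0.21) and also fell in solvent. That is the direction the hypothesis gives, so it stays open for them. Responses at 4 h were not tested for it.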
